A study of Mus musculus with 8 samples.

How the data were processed

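Total RNA of 8 samples of frozen mouse liver was measured by RNA sequencing, 4 with floxed Arid1a alleles (WT) and 4 with the same alleles and Alb-cre (KO), all at postnatal day 90. Per the labels' protocols, RNA was isolated with Trizol and a Qiagen miRNeasy kit and libraries were made with Nugen reagents. The authors deposited 1 table of FPKM values with 35638 Ensembl genes, their symbols and their biotypes. TopHat, edgeR and the build mm10 are named in the submitters' processing notes, without versions. The role of each tool, the program that made the FPKM values, the annotation release and the use of strand are not given in the sources used here. FPKM divides by gene length and by the reads of a library, so a few abundant transcripts lower the values of all other genes. The 10 most abundant genes held 40.9 to 50.4% of the FPKM of a library, and the sums of FPKM ran from 455456 in WT 3 to 621928 in KO 2. The most abundant gene was AY036118, a noncoding gene that overlaps ribosomal RNA, in all libraries except KO 2, where it was Gm23935. The table held 0 genes of the mitochondrial genome, and 8067 genes were at 0 in all 8 libraries.

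Depth was recovered from the steps between low values of 12042 genes with a single annotated transcript, taking transcripts of at least 400 nt. It came to about 12700000, 13400000, 13600000 and 12400000 reads in WT 1 to WT 4 and to 13700000, 15200000, 13700000 and 14800000 in KO 1 to KO 4. With these depths 53.4 to 57.2% of low values lay within 0.1 of a whole number of reads, against 20% by chance, so the depths are estimates and no reads per gene were rebuilt. Of the gene IDs 99.4% (35421) matched the GENCODE M21 annotation of GRCm38, which is the build mm10, and coordinates were taken from it.

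Each column was matched to its sample by name. Values were taken as log2(FPKM + 1), without further scaling, for the 11266 genes with a mean over the 8 libraries of at least 1 FPKM. A fold change is therefore on the log2(FPKM + 1) scale, which understates the change of low genes. The groups were compared with limma 3.58.1 in R 4.3.3 (linear model on genotype, variance moderated with an intensity trend, two-sided), with Benjamini-Hochberg adjustment and a threshold of 0.05. Tests written for counts were not run, since the table holds FPKM. Of 37 gene lists written from textbook knowledge before the data were examined, 29 had at least 3 tested members. They were tested with camera in limma at its preset correlation of 0.01, adjusted over the 29 lists, and again with an estimated correlation and with fry, a rotation test of the list's own genes. Single values per library were compared by exact two-sided permutation over 70 labelled splits, whose smallest p is 0.0286. Plots used Python 3.11.15 with matplotlib 3.10.9.

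Genes were named by a rule fixed before the data were examined. It took Arid1a and any SWI/SNF subunit past the threshold, and the 12 largest rises and 12 largest falls among genes past it without overlap between the groups, leaving out genes with a predicted name. It also took up to 4 members past the threshold in each main list and 3 in each other list, or the member with the smallest p where none passed. The result of 1 gene that this rule takes is not reported here. Other genes in the text were chosen after their values were seen, as background to a list.

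The fit was tested on simulated data for the same comparison of 11266 genes. It recovered 38 of 100 genes changed by 1 on the log2 scale and 78 of 100 changed by 2. Of 120 calls 4 were false (3.33%), and 0 of 20 unchanged lists of independent genes were called. The noise was drawn separately for each gene, so the simulation cannot show how often lists of correlated genes are falsely called. The estimated correlation of the real lists reached 0.88 for macrophage markers and was 0.80 for mitochondrial oxidation. Alternatives fixed beforehand were a pseudocount of 0.1 or 5 FPKM, no filter or a minimum of 5 FPKM, scaling to equal sums, quantile normalization, median ratio scaling, limma without the trend or with array weights, the replicate number as a block, and leaving out each library. Leaving out WT 4 and KO 2 together was added after the data were seen.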

Results

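RNA was sequenced from frozen liver tissue of mice at postnatal day 90, on a mixed background of the C57/B6 and 129 strains. In 4 samples both Arid1a alleles carried loxP sites (WT), and in 4 samples the same alleles were combined with Alb-cre (KO), a transgene that expresses Cre recombinase in hepatocytes. Arid1a encodes a DNA-binding subunit of the SWI/SNF chromatin remodelling complex. The table gave FPKM values (fragments scaled to gene length and library size) for 35638 genes. The steps between low values put the depth at about 12400000 to 15200000 reads per library, with 13000000 ± 550000 in WT and 14400000 ± 750000 in KO (SD, n = 4 each). The comparison asks how loss of Arid1a from hepatocytes alters liver gene expression, with lipid synthesis and fatty acid oxidation as the processes that the series names. Nothing in the labels says that the replicates came from separate animals, so the p-values measure the spread between these samples, which may be technical.

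Arid1a itself (ENSMUSG00000007880, chromosome 4, 133679008 to 133756769, GRCm38) was at 5.16, 8.38, 3.998 and 4.10 FPKM in WT 1 to WT 4 and at 2.70, 2.86, 3.46 and 2.59 FPKM in KO 1 to KO 4. The means were 5.41 ± 2.05 FPKM in WT and 2.90 ± 0.386 FPKM in KO (SD, n = 4 each), and every KO library lay below every WT library. An exact two-sided permutation test gave p = 0.0286, the smallest that 70 labelled splits allow. The log2 change of FPKM + 1 was -0.67 ± 0.23 (SE), with a limma adjusted p of 0.316 over all genes, so Arid1a did not pass the threshold. The values cover the whole gene, the labels do not say which exons are flanked by loxP sites, and other cells of the liver keep the intact gene. Among the 21 SWI/SNF subunits tested, 1 passed the threshold, and 1 did so adjusted over the list alone. This was Smarcb1, a core subunit, which rose from 1.11 ± 0.348 to 4.05 ± 1.19 FPKM (SD, n = 4 each; log2 change 1.24, limma adjusted p = 0.0408, and up to 0.128 when a library was left out). The median change of the list was -0.07 and its mean -0.01, with a camera adjusted p of 0.858.

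The KO samples expressed more of Gsta1, Gsta2, Mup20, H19 and Lpl, and less of Sdr9c7, Abcc3, Oat, Ces1f and Ces2g. Of 11266 genes tested, 46 were higher and 40 lower in KO (limma, Benjamini-Hochberg adjusted p under 0.05), and 1105 had an unadjusted p under 0.05. The 86 genes comprised 76 protein-coding genes, 6 microRNAs, 2 lincRNAs and 2 unprocessed pseudogenes. The counts depended on single libraries. The numbers higher and lower were 20 and 17 without WT 1, 23 and 23 without WT 2, 23 and 19 without WT 3, and 36 and 33 without WT 4. They were 31 and 21 without KO 1, 92 and 44 without KO 2, 21 and 14 without KO 3, and 20 and 19 without KO 4. With WT 4 and KO 2 left out together, a choice made after the data were seen, 75 genes were higher and 35 lower. Of the 86 genes, 25 kept their call whichever of the 8 libraries was left out.

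**Figure D1:**
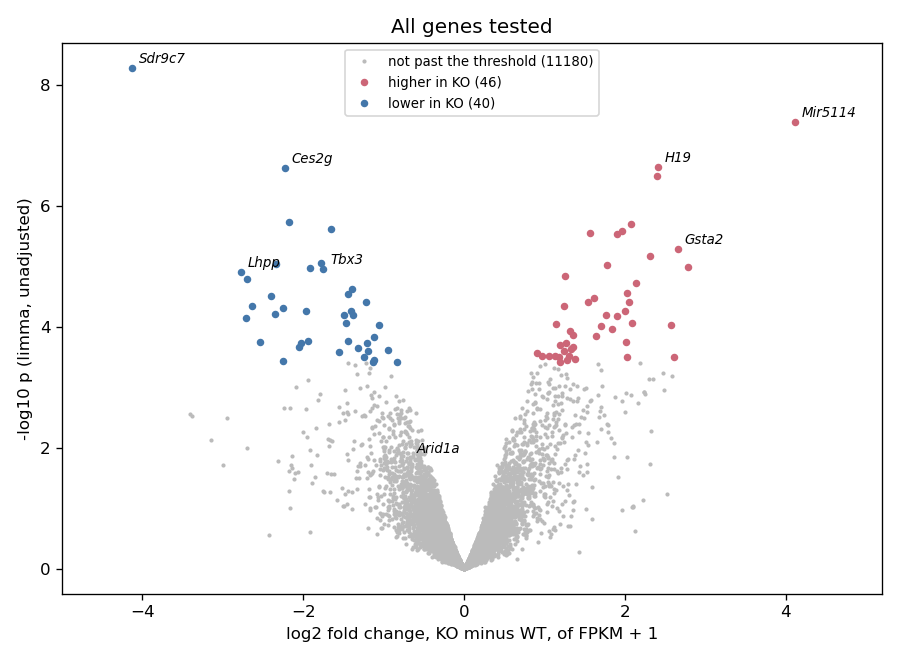
Log2 fold change (KO minus WT, of FPKM + 1) on the horizontal axis against the unadjusted limma p (as -log10) on the vertical axis, with a point for each of the 11266 genes tested. The 46 genes higher in KO and the 40 lower in KO are coloured, and Arid1a lies among the genes that did not pass the threshold.

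H19, an imprinted noncoding RNA of fetal liver, rose from 0.0786 ± 0.0539 to 4.85 ± 1.28 FPKM (log2 change 2.42, limma adjusted p = 6.55e-04). The glutathione transferase genes Gsta1 (0.791 ± 0.252 to 8.51 ± 1.66 FPKM) and Gsta2 (4.004 ± 2.28 to 28.9 ± 5.63 FPKM) rose by 2.40 and 2.66 on the log2 scale. Lpl, the lipoprotein lipase gene, rose from 0.107 ± 0.0592 to 4.19 ± 1.96 FPKM, and Apoc2, which encodes the cofactor of that lipase, from 63.9 ± 25.5 to 277 ± 102 FPKM (SD, n = 4 throughout). Rassf4 (log2 change 2.78), Alpl, the tissue-nonspecific alkaline phosphatase gene (2.62), the MHC class II gene H2-Aa (2.57), Mup-ps19 (2.31), Mup20 (2.08) and Fam47e (2.05) also rose. Mir5114, a microRNA gene inside the Scd2 locus (chromosome 19, 44303171 to 44303231), was listed at 0 in the 4 WT libraries and at 14.1, 9.62, 22.1 and 23.4 FPKM in KO 1 to KO 4, while Scd2 itself did not pass the threshold (limma adjusted p = 0.473). Scd2 was at 16.3 and 11.7 FPKM in WT 1 and WT 2, where Mir5114 was listed at 0, and at 7.23 FPKM in KO 2. Reads of the Gsta and Mup genes can be split between near-identical copies, and Mir5114 overlaps Scd2, so these single values are uncertain. H19, Gsta1, Gsta2, Lpl, Rassf4, Mup-ps19, Mup20 and Mir5114 kept their calls in all 8 fits that left out a library, whereas the limma adjusted p reached 0.1398 for Alpl, 0.0784 for H2-Aa, 0.0784 for Apoc2 and 0.0560 for Fam47e.

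Sdr9c7, a short-chain dehydrogenase gene (ENSMUSG00000040127, chromosome 10, 127898518 to 127911761), fell from 25.1 ± 7.07 to 0.459 ± 0.0850 FPKM (log2 change -4.13, limma adjusted p = 5.85e-05). Abcc3, an exporter of bile acid and drug conjugates, fell from 42.3 ± 11.7 to 6.14 ± 3.90 FPKM. Oat, the ornithine aminotransferase gene of pericentral hepatocytes, fell from 85.6 ± 42.3 to 16.5 ± 4.96 FPKM, and its neighbour Lhpp, a histidine phosphatase gene, from 8.66 ± 3.88 to 0.312 ± 0.205 FPKM. The carboxylesterase genes Ces1f (log2 change -2.72) and Ces2g (-2.23) fell, as did Enho, which encodes the secreted peptide adropin (-2.41), and Slco2a1, a prostaglandin transporter gene (-2.34). Rnf39 (-2.64), Simc1 (-2.54), Obox4-ps2 (-2.35) and Hectd2 (-2.25) completed the 12 falls of largest size. Sdr9c7, Abcc3, Lhpp, Ces2g, Enho and Slco2a1 kept their calls in all 8 fits that left out a library. With the replicate number as a block Lhpp, Abcc3 and Slco2a1 lost them (limma adjusted p = 0.0504, 0.0559 and 0.0732), as did Enho with no filter (0.0621). The limma adjusted p reached 0.145 for Hectd2, 0.112 for Simc1, 0.0678 for Ces1f, 0.0664 for Obox4-ps2, 0.0609 for Rnf39 and 0.0586 for Oat in such fits. The Ces genes have close copies, and the annotated Fgfr2 gene spans Oat and Lhpp, so their values are uncertain to that extent.

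**Figure D2:**
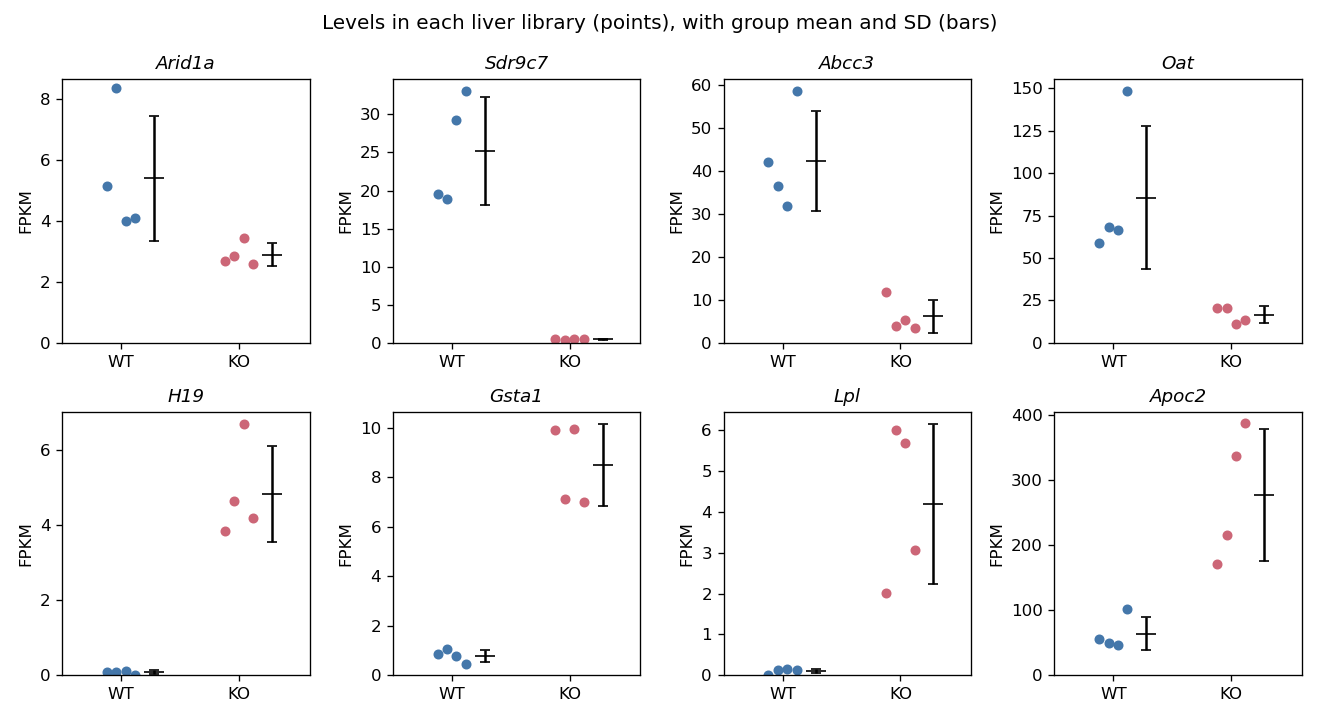
FPKM (vertical axis, from 0) of 8 genes in each of the 4 WT and 4 KO liver libraries (points), with the group mean and SD beside them. The 4 KO libraries lie below the 4 WT libraries for Arid1a, Sdr9c7, Abcc3 and Oat and above them for H19, Gsta1, Lpl and Apoc2.

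Genes of mitochondrial fatty acid oxidation and ketogenesis were lower in KO by their set test. No member passed the threshold over all genes in the main comparison. All 21 tested members had a negative change (median -0.40, mean -0.43, camera adjusted p = 4.26e-06), and the call was lost with an estimated correlation (adjusted p = 0.421 with an estimated correlation). Over all genes 0 passed, and 1 fell when adjusted over the list alone. That member was Acsl1, an acyl-CoA synthetase gene, at 161 ± 42.5 FPKM in WT and 68.2 ± 15.0 FPKM in KO (SD, n = 4 each; limma adjusted p = 0.0507 over all genes). It passed over all genes with equal sums, quantile normalization, median ratio scaling or array weights (limma adjusted p = 0.0289, 0.0167, 0.0345 and 0.0458) and without KO 2 (0.0393). Peroxisomal oxidation genes and PPAR-alpha targets were lower too, with a negative change in 21 of 24 members (median -0.45, mean -0.60, camera adjusted p = 7.60e-05, adjusted p = 0.421 with an estimated correlation), 0 past the threshold over all genes and 0 adjusted over the list alone. Acot1 had the smallest p in this list, at 7.76 ± 6.36 FPKM in WT and 1.70 ± 1.56 FPKM in KO (limma adjusted p = 0.231). WT 4 held the highest values of both lists, with Cyp4a10 at 317 FPKM against 54.3, 47.3 and 41.8 FPKM in WT 1 to WT 3. It also differed in the clock output gene Dbp, at 0.569 FPKM against 42.4, 49.3 and 22.6 FPKM. In KO 2 the mean log2(FPKM + 1) of the oxidation list was 5.81, above 5.74, 5.55 and 5.60 in WT 1 to WT 3. That of the PPAR-alpha list was 4.85 in KO 2, above 4.73, 4.50 and 4.46 in WT 1 to WT 3. Exact permutation of the list means over all libraries gave p = 0.143 for each list. Without WT 4 the mean change of the oxidation list was -0.26 (camera adjusted p = 8.44e-04) and that of the PPAR-alpha list -0.37 (camera adjusted p = 0.00288), against -0.43 and -0.60 with all libraries.

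Fatty acid and triglyceride synthesis genes were slightly higher in KO by their set test only, with no member past the threshold. Of 23 tested members 15 had a positive change (median 0.21, mean 0.33, camera adjusted p = 0.0329, adjusted p = 0.660 with an estimated correlation), and 0 passed over all genes or adjusted over the list alone. Scd2, a stearoyl-CoA desaturase gene, was at 9.47 ± 5.79 FPKM in WT and 27.6 ± 16.9 FPKM in KO, and Fasn, the fatty acid synthase gene, at 157 ± 53.7 and 321 ± 184 FPKM (SD, n = 4 each; limma adjusted p = 0.473 and 0.754). The call was lost with an estimated correlation, without WT 4 (camera adjusted p = 0.655, mean 0.10) and without KO 1 (camera adjusted p = 0.676, mean 0.12). Exact permutation of the list means over all libraries gave p = 0.343. The mean log2(FPKM + 1) of the list was 5.17 in KO 2, below 5.99, 5.84 and 5.96 in WT 1 to WT 3, and 5.01 in WT 4. Fasn was at 72.4 FPKM in KO 2 and at 342 FPKM or more in the other KO libraries. Lipoprotein assembly and export genes had a positive change in 16 of 18 members (median 0.19, camera adjusted p = 4.42e-04, adjusted p = 0.421 with an estimated correlation). Apoc2 rose over all genes, and 4 members rose when adjusted over the list alone. Among 10 lipid droplet and PPAR-gamma steatosis genes, Lpl rose over all genes and 2 rose when adjusted over the list alone. The median of that list was -0.11 and its mean 0.25, of opposite sign, and it was not called (camera adjusted p = 0.345). Of 23 cholesterol synthesis and SREBP2 target genes 0 passed over all genes or adjusted over the list alone (median -0.17, camera adjusted p = 0.428). With WT 4 and KO 2 left out together the mean of that list turned from -0.11 to 0.27 and was called (camera adjusted p = 0.0324).

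Targets of NRF2 and oxidative stress were higher by their set test, with a positive change in 10 and a negative change in 6 of 16 tested members. Over all genes 5 rose, namely Gsta1, Gsta2, Gstm3 (32.0 ± 6.76 to 95.1 ± 20.6 FPKM), Gsta4 (16.1 ± 2.91 to 36.4 ± 3.45 FPKM) and the efflux transporter gene Abcc4 (0.422 ± 0.356 to 2.50 ± 0.475 FPKM; SD, n = 4 each). Adjusted over the list alone, 6 rose and 1 fell (camera adjusted p = 9.98e-07, adjusted p = 0.114 with an estimated correlation). Nqo1 had a change of -0.76 and Gclc of -0.13, and neither of these common NRF2 targets passed over all genes. Interferon-stimulated genes had a positive change in all 12 tested members (median 0.69, camera adjusted p = 8.34e-13, adjusted p = 0.130 with an estimated correlation). Irf7, a transcription factor of the interferon response, rose from 3.22 ± 1.13 to 13.3 ± 3.43 FPKM, Oas1a rose by 1.20 and Gbp2 by 1.35 on the log2 scale, and 8 members rose when adjusted over the list alone. Macrophage markers had a positive change in the same libraries (median 2.17, 11 of 11 members). In KO 4 the mean log2(FPKM + 1) of the interferon-stimulated genes was 3.18, apart from 2.59 to 2.62 in the other KO libraries. The calls of Irf7, Oas1a, Gbp2, Gstm3, Gsta4 and Abcc4 were each lost in at least 1 fit that left out a library, with limma adjusted p up to 0.0690, 0.110, 0.123, 0.0546, 0.0843 and 0.0937. Of 22 xenobiotic metabolism genes Cyp3a11 fell from 317 ± 51.0 to 116 ± 33.1 FPKM, while 2 rose and 2 fell adjusted over the list alone and the list was not called (camera adjusted p = 0.390), although it was called lower without KO 2 (camera adjusted p = 0.0493) and without WT 4 and KO 2 together (0.0117). Cyp3a11 has close copies, and its limma adjusted p reached 0.0786 when libraries were left out. Of 23 bile acid synthesis and transport genes Abcc3 fell and Abcc4 rose, over all genes and adjusted over the list alone. The median of that list was 0.08, its mean -0.17 and the direction of its test up (camera adjusted p = 0.975). Of 22 glucose metabolism genes 0 passed over all genes and 1 fell adjusted over the list alone (median -0.04, test direction up, camera adjusted p = 0.936). That gene was G6pc, the catalytic subunit of glucose-6-phosphatase, at 133 ± 39.1 FPKM in WT and 54.0 ± 15.8 FPKM in KO (limma adjusted p = 0.0892).

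Pericentral hepatocyte genes were lower and periportal hepatocyte genes higher in KO by their set tests. Of 16 pericentral genes 14 had a negative change (median -0.67, camera adjusted p = 1.71e-06, adjusted p = 0.250 with an estimated correlation), 2 fell over all genes and 3 adjusted over the list alone. Tbx3, a transcription factor gene of pericentral hepatocytes, fell from 6.16 ± 1.20 to 1.14 ± 0.457 FPKM (SD, n = 4 each) along with Oat. WT 4 stood apart in this list, with a mean log2(FPKM + 1) of 5.51 against 5.06 to 5.08 in the other WT libraries, and in Oat, at 149 FPKM against 58.8 to 68.3 FPKM. Without WT 4 the mean change of the list was -0.75 in place of -0.86 and the list was still called by camera, and Oat still fell (limma adjusted p = 0.0165). Cyp2e1, a pericentral cytochrome P450 gene, was at 1315 ± 338 FPKM in WT and 388.2 ± 266 FPKM in KO (limma adjusted p = 0.0748). Of 20 periportal genes 18 had a positive change (median 0.26, camera adjusted p = 1.27e-04, adjusted p = 0.328 with an estimated correlation). The groups overlapped in the periportal list, with a mean log2(FPKM + 1) of 6.32 in KO 1, below 6.52 in WT 1 and 6.58 in WT 3. Its exact permutation p was 0.114, against 0.0286 for the pericentral list. Aldh1b1, an aldehyde dehydrogenase gene, rose from 17.8 ± 3.85 to 63.5 ± 13.7 FPKM, and 3 rose and 1 fell adjusted over the list alone. Hepatocyte identity factors and secreted products were not called, with 0 of 25 past the threshold over all genes or adjusted over the list alone (median 0.05, camera adjusted p = 0.435). Prox1 had the smallest p there, at 32.8 ± 4.38 FPKM in WT and 20.6 ± 5.87 FPKM in KO (limma adjusted p = 0.349).

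Fetal liver and hepatocellular carcinoma markers were higher by their set test (5 tested, median 1.39, mean 0.69, camera adjusted p = 0.0154, adjusted p = 0.250 with an estimated correlation). Over the 11 members above 0 in any library the median was 0.13. H19 and Tff3, a trefoil factor gene listed at 0 in the 4 WT libraries and at 2.03 to 3.82 FPKM in KO, rose, and 3 rose and 2 fell adjusted over the list alone. Afp, the alpha-fetoprotein gene, was at 1.81 ± 1.36 FPKM in WT and 0.588 ± 0.5004 FPKM in KO (SD, n = 4 each). The call of the list was lost without WT 4 (camera adjusted p = 0.153) and with array weights (0.0548). All 5 tested cell cycle and mitosis genes had a positive change (median 0.79, camera adjusted p = 2.50e-04, adjusted p = 0.222 with an estimated correlation), with 0 past the threshold over all genes or adjusted over the list alone. Over all 21 members, most of them under the minimum for testing, the median was 0.33. Macrophage, endothelial and stellate cell markers were higher in the same libraries (medians 2.17, 1.01 and 1.10). Mcm3, a replication helicase gene, was at 0.999 ± 0.279 FPKM in WT and 3.17 ± 1.75 FPKM in KO (limma adjusted p = 0.266). Of 8 p53 targets and cell cycle inhibitors 0 passed over all genes or adjusted over the list alone, Ccng1 having the smallest p (6.21 ± 1.88 and 9.54 ± 1.72 FPKM). The set test gave a camera adjusted p of 0.0330 (median 0.49, adjusted p = 0.378 with an estimated correlation), and 0.0632, 0.0604 and 0.250 without WT 1, WT 2 and KO 1. Female-biased liver genes had a negative change in 14 of 19 members (median -1.56, camera adjusted p = 1.15e-04, adjusted p = 0.304 with an estimated correlation). Fmo2, a flavin monooxygenase gene, fell from 6.84 ± 2.70 to 1.56 ± 0.409 FPKM (limma adjusted p up to 0.125 when a library was left out), and 7 members fell adjusted over the list alone. Cyp2b9 of this list was at 0 FPKM in WT 4 and at 129 to 234 FPKM in WT 1 to WT 3. The mean log2(FPKM + 1) of the female-biased list was 3.51 in WT 4, below 4.18 in KO 2 and 3.53 in KO 4. Exact permutation of these means over all libraries gave p = 0.0857. Of 12 male-biased genes Mup20 rose and Cyp2u1 fell by 1.11 over all genes (limma adjusted p up to 0.0992 when a library was left out), 2 rose and 1 fell adjusted over the list alone, and the list was not called (camera adjusted p = 0.830). Immediate early and heat shock genes had a negative change in 12 of 16 members (median -0.31, camera adjusted p = 0.00700, adjusted p = 0.421 with an estimated correlation), with 0 past the threshold over all genes or adjusted over the list alone, and without WT 1 the call was lost (camera adjusted p = 0.104). Ier2 had the smallest p of this list, at 69.4 ± 11.3 FPKM in WT and 42.7 ± 6.09 FPKM in KO (limma adjusted p = 0.167).

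Markers of macrophages, sinusoidal endothelial cells and quiescent stellate cells were higher in KO by their set tests. All 11 tested macrophage and Kupffer cell markers had a positive change (median 2.17, or 1.21 over all 20 members, camera adjusted p = 2.00e-16, adjusted p = 0.133 with an estimated correlation), with 0 past the threshold over all genes and 11 adjusted over the list alone. The Kupffer cell genes Cd5l and Clec4f were at 1.89 ± 0.644 and 2.58 ± 0.641 FPKM in WT and at 19.98 ± 12.5 and 18.4 ± 11.5 FPKM in KO (SD, n = 4 each; limma adjusted p = 0.0692 and 0.114). KO 2 had the lowest values of both in its group, at 4.02 and 3.79 FPKM, and Cd5l passed over all genes without KO 2 (log2 change 3.17, limma adjusted p = 0.00259) and without WT 4 and KO 2 together (0.00461). All 12 sinusoidal endothelial markers had a positive change (median 1.01, camera adjusted p = 3.94e-16, adjusted p = 0.130 with an estimated correlation), of which Dnase1l3 rose over all genes (0.611 ± 0.142 to 3.14 ± 1.17 FPKM, limma adjusted p up to 0.137 when a library was left out) and 12 adjusted over the list alone. All 6 tested quiescent stellate cell markers had a positive change (median 1.10, or 0.66 over all 11 members, camera adjusted p = 3.34e-06, adjusted p = 0.130 with an estimated correlation), with 0 past the threshold over all genes and 5 adjusted over the list alone. Ecm1 was the stellate marker with the smallest p (2.74 ± 0.777 and 7.26 ± 2.48 FPKM), and it passed over all genes without KO 2 (limma adjusted p = 0.0419) and without WT 4 and KO 2 together (0.0490). Only 3 of 23 fibrosis and activated stellate cell genes reached the minimum for testing, and these had a median change of 1.42, against 0.24 over all 23 on the same scale (camera adjusted p = 2.62e-04, adjusted p = 0.114 with an estimated correlation), 0 past the threshold over all genes and 3 adjusted over the list alone. Dcn, the decorin gene, was at 2.33 ± 1.76 FPKM in WT and 9.32 ± 3.21 FPKM in KO, and the collagen gene Col1a1 was at 0.0179 ± 0.0289 and 0.195 ± 0.178 FPKM, under the minimum for testing. On the scale of log2(FPKM + 0.1), which compresses low values less, the mean change of all 23 was 1.07 (exact permutation p = 0.0286). Over all genes Dcn was called without WT 4 (limma adjusted p = 0.0273), with array weights (0.0396) and without WT 4 and KO 2 together (0.0392). None of the 17 list calls held with an estimated correlation.

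**Figure D3:**
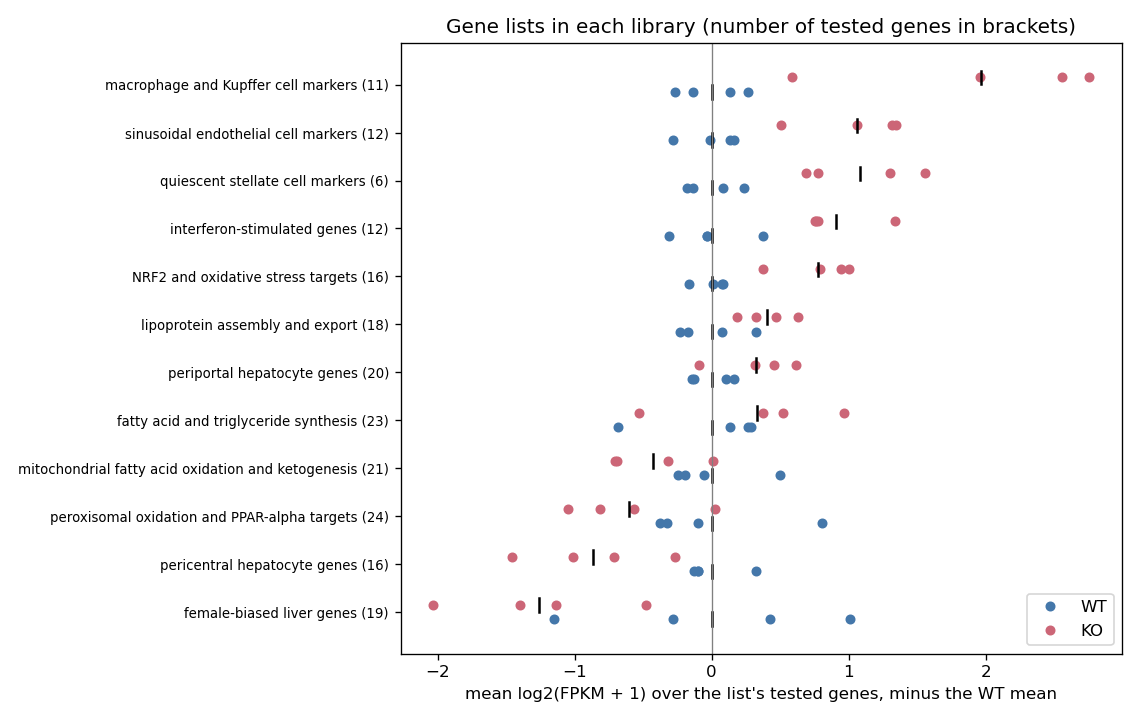
Mean log2(FPKM + 1) over the tested genes of 12 gene lists in each of the 4 WT and 4 KO libraries, as the difference from the WT mean (horizontal axis; the black ticks are group means). The macrophage marker list lies 1.97 above WT on average and the female-biased list at -1.26, and WT 4 is the WT library farthest to the right in both oxidation lists.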

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

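The comparisons of the 8 libraries with each other and the tests on the oxidation lists and on the cell type markers were chosen after the results were seen, whereas the count over other splits of the libraries was set before it was run. Of 178 groups of 4 libraries examined (each named gene and each tested list, in WT and in KO), 12 held a library whose gap to the nearest other exceeded the critical share of the range in Dixon's test, where chance gives about 1 in 20, or 8.9. WT 4 was the library in 6 of the 12. In WT 4 the mean log2(FPKM + 1) was 5.01 for fatty acid and triglyceride synthesis (5.84 to 5.99 in the other WT libraries), 6.99 for acute phase proteins (6.01 to 6.15), 5.51 for pericentral genes (5.06 to 5.08) and 2.24 for circadian clock genes (3.56 to 3.69). Oat was at 149 FPKM and Smarcb1 at 1.63 FPKM in WT 4, above 58.8 to 68.3 and 0.884 to 0.980 FPKM in the other WT libraries.

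In KO 3 Alpl was at 2.26 FPKM, against 14.3 to 15.1 FPKM in the other KO libraries, and the mean of bile acid genes was 4.71 against 5.12 to 5.17. In KO 4 Gbp2 was at 6.19 FPKM against 2.76 to 3.14 FPKM, and the mean of interferon-stimulated genes was 3.18 against 2.59 to 2.62. Lpl was at 0.0191 FPKM in WT 1 against 0.127 to 0.148 FPKM, and Obox4-ps2 was at 0.205 FPKM in KO 2 and listed at 0 in the other KO libraries.

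Of the 35 splits of the 8 libraries into 4 and 4, only 1, the real one, gave as many as 86 called genes. The highest of the others gave 7. A random grouping of these 8 libraries is thus an unlikely source of that count, at the level of 0.05. This share of splits is the smallest that the test allows. It does not cover differences between the groups other than genotype, nor any single gene. For the 17 gene lists called by camera the real split was again the only 1 of the 35 splits to reach its count, and the highest of the others gave 16. That count came from splits with 3 WT libraries on one side and 3 KO libraries on the other. Splits with 2 libraries of each genotype on both sides gave 3 to 10 lists.

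Genes of fatty acid oxidation and PPAR-alpha targets were lower in KO by their set tests. WT 4, which stood apart in clock genes, held the highest WT values, and KO 2 lay above WT 1 to WT 3 in both lists. If WT 4 had been taken at another clock phase or feeding state, it may account for part of the difference, since the mean change of the oxidation list was -0.26 without WT 4 and -0.43 with it. WT 4 does not enter the fit that gave -0.26, so its state cannot be the source of that part, which was called at the preset correlation (camera adjusted p = 8.44e-04) but not with an estimated correlation (adjusted p = 0.574, and 0.421 with all libraries) nor by exact permutation of the 7 libraries (p = 0.257). A lower share of hepatocyte RNA in KO as the whole cause would lower the 25 hepatocyte identity genes by about as much. The difference between the oxidation and identity lists, with the spread of both counted, was -0.46 with an exact permutation p of 0.0857. By the rule set for this test a p of 0.05 or more counts for that cause. With 4 libraries in each group such a p cannot show that both lists fell alike, so this test does not settle it. A further test took the fall of the oxidation list as fixed, which leaves out its spread. In that test the mean change of the identity genes, 0.03, lay 0.46 above the fall (exact permutation p = 0.0286). Their median of 0.05 was above it by more than the SD of their changes (0.24). Periportal genes (18 of 20) and lipoprotein genes (16 of 18) mostly had positive changes. The difference between the oxidation and lipoprotein lists, with the spread of both counted, was -0.83 (exact permutation p = 0.0286). Between the oxidation and periportal lists it was -0.75 (exact permutation p = 0.0571). Measured against lipoprotein genes, this argues against a lower hepatocyte share as the whole cause of the oxidation list's fall. Pericentral genes fell further (mean -0.86). An effect of the genotype and a smaller pericentral part of the tissue also stay open, the latter untested.

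Macrophage and sinusoidal endothelial markers were higher in KO, with a median change of 1.28 over 23 tested markers. The greater depth of the KO libraries does not account for it, since the highest median among 10000 random gene lists matched on mean level was 0.26. A lower share of hepatocyte RNA may account for it, and would raise both lists alike. Over all members above 0 the macrophage list rose by 2.09 and the endothelial list by 1.77 (log2(FPKM + 0.1)). Their difference of 0.32 had an exact permutation p of 0.343. Such a p does not show that the rises were equal, and more of both cell types could also give it, so the test does not favour this cause. Quiescent stellate markers moved the same way (1.56), while cholangiocyte markers (-0.03) and lymphocyte markers (0.33) lay near the floor, at median levels of 0.0299 and 0.0142 FPKM in WT. A change within macrophages and endothelial cells, or more of them in KO liver tissue, also stays open, and hepatocyte identity genes had a mean change of 0.03.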

How the results depend on the processing

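The direction of a list is that of its set test where it was called and otherwise that of its mean log2 change, a definition settled after the values were seen. Of 1106 recomputed values of named genes 893 kept their direction and side of the threshold, 188 kept direction and lost the call, 16 gained one and 9 reversed. For lists these were 511, 38, 25 and 28 of 602. All 21 settings kept the direction of both oxidation lists and of fatty acid synthesis. Among these, the estimated correlation and fry reuse the means of the main fit, so their directions could not differ there. All settings with a value kept the direction of Arid1a (limma adjusted p 0.195 to 0.493). With all 8 libraries, 11 of the 86 called genes kept their call under every other setting. The causes below were not tested, except that stricter filters test fewer genes and left-out libraries leave fewer samples.

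The number of genes higher in KO (46) was 27 with a pseudocount of 5 FPKM, 14 with a filter of mean 5 FPKM, 20 to 92 without single libraries and 75 with WT 4 and KO 2 left out together. The number of genes lower in KO (40) was 26 with no filter, 13 with a filter of mean 5 FPKM and 14 to 44 without single libraries. The gene list tests called 17 lists, 0 with an estimated correlation and 7 with fry. Scaling to the same sum moved the median change of all genes from -0.03 to -0.13. The correlations of deviations did not show that the replicate numbers pair the samples, and they cannot exclude it. Same-numbered libraries correlated at -0.07 to 0.25, with a mean of 0.07 against -0.02 for other numbers. The value of 0.25 was that of WT 4 with KO 4, and not every library correlated best with its own number. With the replicate block 16 genes were higher and 8 lower.

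The mean of fatty acid and triglyceride synthesis (0.33) was no longer called with an estimated correlation or fry (adjusted p 0.660 and 0.681), with no filter (0.32), quantile normalization (0.35) or array weights (0.16), and ran from 0.10 to 0.62 without single libraries. That of mitochondrial oxidation (-0.43) lost its call with an estimated correlation and fry (adjusted p 0.421 and 0.244).

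The means of these lists and genes changed sign. SWI/SNF subunits (-0.01) were at 0.025 with a pseudocount of 0.1, 0.011 with quantile normalization, 0.0069 with median ratio scaling, 0.0041 with array weights, 0.036 without both libraries and -0.052 to 0.021 without single ones. Circadian clock genes (0.03) were at -0.0024 with no filter, -0.071 with equal sums, -0.13 with array weights, -0.39 without both libraries (camera adjusted p = 0.00111) and -0.31 to 0.17 without single ones (-0.31 without WT 4, camera adjusted p = 0.00395). Hepatocyte identity factors (0.03) were at -0.082 with equal sums, -0.0096 with quantile normalization and -0.047 to 0.12 without single libraries. Male-biased genes (-0.14) were at 0.17 with a filter of mean 5 FPKM, 0.047 without both libraries and -0.28 to 0.17 without single ones. Cholesterol synthesis genes (-0.11) were at 0.27 without both libraries (camera adjusted p = 0.0324) and -0.25 to 0.10 without single ones, and acute phase proteins (0.28) at -0.011 to 0.53. Tsix (0.05) was at -0.060 with equal sums, -0.0051 with array weights, -0.061 without both libraries and -0.062 to 0.15 without single ones. Alas2 and Cela1 were at -0.078 to 0.21 and -0.059 to 0.47 without single libraries. Depth limits what can be seen of low genes, and 38 of 100 simulated changes of 1 were recovered.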

Other observations

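The test of neighbouring genes was chosen after the called genes were seen, and so were the genes named here. Outside the named genes and lists, Mpeg1, which encodes a pore-forming protein of macrophages, was at 14.7 FPKM in KO (5.49 times WT) and the leukocyte actin-bundling gene Lcp1 at 8.67 FPKM (7.22 times WT). Tgfbr2, the TGF-beta type II receptor gene, was 4.31 times and Igfbp7 4.25 times WT, and Srd5a1, a steroid reductase gene, 3.50 times. Among the falls, the prolactin receptor gene Prlr was at 0.396 of WT, the mitochondrial isocitrate dehydrogenase gene Idh2 at 0.503, the activin subunit gene Inhbc at 0.214 and the bile acid transporter gene Slc10a2 at 0.260 (limma, adjusted p under 0.05 in each case).

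Acute phase proteins (20 tested, median 0.15, camera adjusted p = 0.0510), inflammatory cytokines and NF-kB targets (6 tested, median 0.27, camera adjusted p = 0.0531), unfolded protein and integrated stress response genes (14 tested, median -0.37, camera adjusted p = 0.109) and circadian clock genes (14 tested, median 0.12, test direction down, camera adjusted p = 0.839) were not called. All of them were called under some alternatives. Acute phase proteins were called higher without KO 1, KO 2 or WT 4 (camera adjusted p = 4.50e-04, 0.0398 and 0.00329), with WT 4 and KO 2 left out together (0.00222), and with either other pseudocount, equal sums, median ratio scaling, array weights or the replicate block (0.0117 to 0.0497). Inflammatory genes were called higher without WT 1, WT 2, WT 3, KO 1 or KO 4 (0.00975, 0.0149, 0.0458, 0.0328 and 0.0138), with no filter (5.79e-06), with equal sums (0.0332) and with a pseudocount of 0.1 FPKM (0.0488). The stress response genes, with a negative change in 12 of 14, were called lower with no filter (0.00285), a filter of mean 5 FPKM (0.0453), the replicate block (0.0131), without WT 2 (0.0407) and without KO 4 (0.00844), where their mean was -0.55 in place of -0.32. Clock genes were called lower without WT 4 (mean -0.31 in place of 0.03, camera adjusted p = 0.00395) and with WT 4 and KO 2 left out together (0.00111). No member passed the limma threshold over all genes in these lists, where the smallest p belonged to Orm3, Cxcl9, Sesn2 and Hlf (adjusted p = 0.164, 0.0664, 0.548 and 0.206). Orm3 passed without KO 4 (0.0266), and Cxcl9 without KO 2 (0.0364), with quantile normalization (0.0433) and with median ratio scaling (0.0493). Adjusted over the list alone, 2 rose and 1 fell among acute phase proteins and among inflammatory genes, and 0 in the other lists. Lymphocyte, neutrophil and mitochondrial genome lists had 0 members at the minimum for testing. Among lists with 1 or 2 tested members, Car3 fell from 515 ± 118 to 140.1 ± 52.9 FPKM (SD, n = 4 each; limma adjusted p up to 0.113 when a library was left out), while Spp1, Alas2 and Cela1 had limma adjusted p of 0.235, 0.947 and 0.958. Xist was at 53.5 to 95.6 FPKM in the 8 libraries and the Y-linked gene Ddx3y at 0 in all but KO 4 (0.0527 FPKM), and Tsix had a limma adjusted p of 0.975.

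Called genes lay next to each other more often than random genes, with 21 of the 86 having another called gene within 200 kb against a mean of 3.85 and a highest value of 16 in 10000 draws. They include Gsta4, Gsta1 and Gsta2 on chromosome 9 (all higher), Rdh16, BC089597 and Sdr9c7 on chromosome 10 (all lower), Oat and Lhpp on chromosome 7 (lower), and H19 with Mir675 inside it. Reads shared between overlapping or related genes may account for much of this, but the test depends on how families are drawn. Leaving out pairs that overlap or belong to the same family left 9 genes (reached in a share of 0.0296 of draws). Families were drawn by the leading letters of the symbols, with Rdh16, BC089597, Sdr9c7 and related genes put in the same family by hand. Counting predicted genes inside a family as members, a definition changed after that first count was seen, left 2 (share 0.823). Strain variants linked to the genotype cannot be told apart from the other explanations for the 21 genes, because a table of gene levels holds no variants.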
